A study of Cereibacter sphaeroides with 6 samples.

How the data were processed

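Total RNA of 6 samples of Rhodobacter sphaeroides 2.4.1 was measured, each on its own array. Per the labels, the RNA of the 100 W samples and of 10 W replicate 1 was made by boiling lysis and hot phenol extraction. The deposited values are 1 intensity per probe set and array on a linear scale. The software that made them, the background correction and detection calls are not given in the sources used here. From the values, the mean of each array without its 2% highest and 2% lowest intensities was 500.1, so each array had been scaled to one common level, and such a scale fixes the average and leaves room for differences in shape. The 99th percentile of intensity was 10018, 10108 and 10706 on the 10 W arrays and 7525, 8186 and 8372 on the 100 W arrays, while the medians were 191.1 to 217.5 and 220.8 to 227.4. No 2 arrays held the same values throughout: each pair shared 5 to 17 identical values of 5355.

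Samples were grouped by the illumination in their titles. The replicate numbers come from the same titles. The gene lists, the tests, the rule for named genes and the alternatives in the plan were fixed before the data were examined. Where a test or setting was chosen later, the closing section names it.

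The scale of the deposited values was kept, because the trimmed means of the arrays differed by less than 10%. Intensities under the 5th percentile of all values (12.8) were set to it before log2, which applied to 1601 of 32130 values (4.98%). A fold against a value near that floor depends on the floor. Probe sets in the lowest 25% of mean log2 intensity were left out, which left those above an intensity of about 82.5, 4014 in number. The 3 recognised control probe sets, for thrC of Bacillus subtilis, were left out of the test. Probe sets are numbered without a mark for controls, so other controls may be among the unnamed ones. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), Benjamini-Hochberg adjusted, at an adjusted p under 0.05. Signed values are 100 W minus 10 W. Means and SDs are of the deposited intensities. Fold changes are from the log2 scale with the floor.

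The platform annotation listed 542 of the 5355 probe sets, 539 with 1 gene symbol each, 0 with several, and the 3 controls. The other 4813 have no name here. These names can be old. None of the annotation's gene IDs was found in the reference gene table (assembly ASM332471v1), which gave gene lengths by symbol for 408 of the 466 tested named genes (87.6%) and no coordinates. Of genes with several probe sets (10 genes), the probe set with the highest mean log2 intensity stood for the gene.

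The 24 gene lists were matched by symbol, and lists of at least 3 tested genes (18) were tested with camera of limma at its preset correlation of 0.01 against the 466 named genes, Benjamini-Hochberg adjusted over the lists. That background was settled after the values were seen. Since most probe sets have no name, each list holds only part of its pathway. None of the 4 lists called passed when camera estimated the correlation between genes. The named genes were the 8 steepest rises and the 8 steepest falls among named probe sets past the threshold without overlap between groups, up to 2 rises and 2 falls in each list that passed camera or had at least 3 called members, and a set named in advance. Of that set pufB, pucA, pucB, prrA, cbbM and cbbL are not analysed here, since no probe set used here carries those names. Single genes of other lists with fewer than 3 tested members, and bchF in a caption, were chosen after their values were seen.

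Alternatives were quantile normalization, median centring, no filter or a filter on the lower 50% of probe sets, no floor, a pseudocount of 84.5 in place of the floor, other variance priors, a replicate block, each array left out in turn, a stricter threshold, and for lists an estimated correlation, fry and the mean of all probe sets of a gene. A planned comparison of replicons was not run, since no table used here places the probe sets on them. The procedure was tested on simulated data for the comparison of 3 against 3 arrays over 4014 probe sets in 20 rounds, with 200 probe sets changed. It recovered 34.1% of changes of 0.5 on the log2 scale, 76.6% of changes of 1 and 96.2% of changes of 2, with 4.29% false calls. Far more probe sets were called in the data (2118), so these rates describe the simulated setting and need not hold for the data. A list of 10 genes shifted by 0.5 was called in 20 of 20 rounds and an unshifted one in 2.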

Results

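Transcript levels were measured on oligonucleotide arrays in Rhodobacter sphaeroides 2.4.1 (now Cereibacter sphaeroides), a purple non-sulfur bacterium that grows photosynthetically without oxygen. The cultures were sparged with a mixture of 95% nitrogen and 5% carbon dioxide, and grew either at 10 W per square metre under lumiline bulbs or at 100 W per square metre under tungsten bulbs. Each group had 3 arrays. The 100 W cultures were taken at an optical density at 600 nm of 0.4, and the density of the 10 W cultures is not given in the sources used here. Each array held 5355 probe sets, of which 539 carried a gene name in the platform annotation used here, standing for 514 genes. The number of arrays limits the precision of every value. The labels do not say whether the 3 arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. Across probe sets, Pearson's r between arrays of one group was 0.965 to 0.976 at 10 W and 0.979 to 0.984 at 100 W, against 0.809 to 0.837 between the groups. The median standard deviation per probe set was 0.176 on the log2 scale at 10 W and 0.143 at 100 W.

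The comparison asked how the level of illumination changed transcript levels. Genes of the flagellum and of NADH dehydrogenase were higher at 100 W, and genes of the photosynthetic reaction centre, its core antenna and the regulators of photosynthesis were lower. These 4 list calls were made by camera at its preset correlation of 0.01. When camera estimated the correlation, adjusted p = 0.117, 0.176, 0.382 and 0.121 for flagellum, NADH dehydrogenase, reaction centre with core antenna, and regulators. The estimated correlations, in that order, were -0.00178, -0.0145, 0.514 and -0.0841. Only that of the reaction centre list was above the preset, so for the other lists a higher correlation does not account for the lost call. The reaction centre and core antenna list also lost its call after quantile normalization (median log2 change of -0.18, camera adjusted p of 0.0903), where pufL and pufM turned positive. Of 4014 probe sets tested, 2118 (52.8%) changed with a limma adjusted p under 0.05. Of these, 1180 were higher and 938 lower at 100 W, so that 55.7% of the changed probe sets were higher. After median centring of each array that share was 42.6%, with the median log2 change over all tested probe sets at -0.11 in place of 0.04, so small changes have a direction only relative to the scaling. A change of at least 2-fold was found for 715 probe sets, 411 higher and 304 lower, which median centring turned to 319 higher and 396 lower. Among the 466 named genes tested, 181 rose and 94 fell, with a median log2 change of 0.19. Camera sets each list against these genes, so a list with a small positive median can test negative. The illumination coincided with the type of bulb and with the month in the sample titles, so these cannot be told apart.

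The steepest rises among named genes above the filter on intensity were those of flagellum genes. Of 12 flagellum genes tested, 11 rose at 100 W (11 adjusted over the list alone) and none fell, with a median log2 change of 3.08. The intensity of flgG, which encodes the distal rod protein (probe set 943), was 25.6 ± 17.3 at 10 W and 1058 ± 88 at 100 W (SD, n = 3), a log2 change of 5.53 ± 0.35 (SE) and a limma adjusted p of 2.07e-08. The stator gene motA (probe set 1101) went from 106.3 ± 11.1 to 1604 ± 104, a 15.1-fold rise. The export gene flhA rose 14-fold, the rod gene flgC 9.31-fold, and flgM, the gene of an anti-sigma factor, 9.24-fold. The switch gene fliM gave a divided result: its probe set 922 rose 31.2-fold, from 18.8 ± 6.8 to 564.7 ± 43.8, while its brighter probe set 921, which stood for the gene in the list, was at 503.2 ± 43.8 and 541.1 ± 47.4. The list as a whole was higher than other named genes by camera (adjusted p = 1.94e-05), with an adjusted p = 0.117 with an estimated correlation. Several of these genes lay near the lowest intensities at 10 W, and with 84.5 added to each intensity before the logarithm the rises were 10.4-fold for flgG, 6.28-fold for probe set 922 of fliM, 8.85-fold for motA, 4.77-fold for flhA and 4.67-fold for flgC. Without 10 W replicate 3 the rise of flgC was 5.42-fold.

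**Figure D1:**
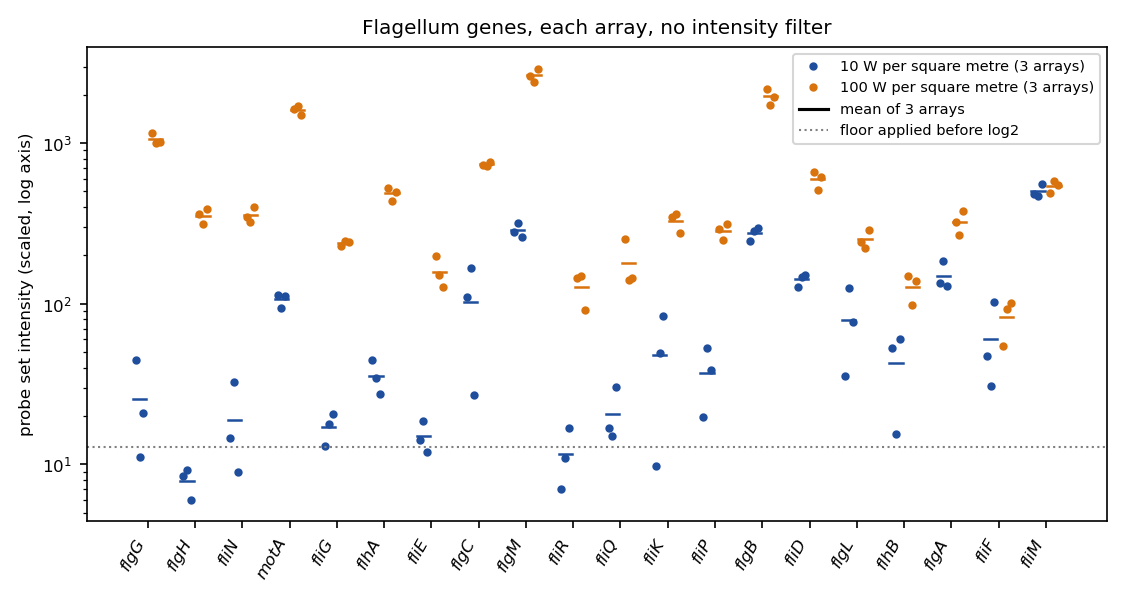
Intensity (log axis) of the 20 named flagellum genes on each of the 3 arrays at 10 W (blue) and at 100 W (orange), with the mean of each group as a bar and the floor of 12.8 as a dotted line. No filter on intensity was applied here, and 17 of the 20 genes rose at 100 W.

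Also among the 8 steepest rises of named probe sets above the filter were traU and traL, genes of conjugative transfer. The intensity of traU went from 26.5 ± 6.1 to 345.2 ± 88.2 and that of traL from 243.5 ± 46.8 to 2111 ± 226 (SD, n = 3), with limma adjusted p of 3.67e-07 and 7.61e-10. With the added intensity of 84.5, the 13-fold rise of traU became 3.82-fold.

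The genes of the photosynthetic apparatus went the other way. All 6 named genes in the list of the reaction centre and the core antenna LH1, which takes in pufQ, fell at 100 W (6 adjusted over the list alone), with a median log2 change of -0.78. The antenna gene pufA (probe set 1130) was at 21530 ± 3570 at 10 W and 12120 ± 1960 at 100 W (SD, n = 3), a log2 change of -0.83 ± 0.14 (SE, limma adjusted p = 0.000229). The reaction centre genes pufL, pufM and puhA had log2 changes of -0.54, -0.65 and -0.73, and pufQ, a gene that acts in bacteriochlorophyll formation, of -0.94. The list was lower than other named genes by camera (adjusted p = 0.000306), with an adjusted p = 0.382 with an estimated correlation. These are among the brightest probe sets on the arrays. The 55 probe sets with a mean log2 intensity above 13 had a median log2 change of -0.63, but they include those of pufA, pufL, pufM and puhA. Probe sets outside the photosynthesis lists matched to the 6 genes in intensity had a median of -0.52 (77 probe sets). Those without a name may still be photosynthesis genes. After quantile normalization the list had a median of -0.18 and a camera adjusted p of 0.0903. There probe set 1130 of pufA was at -0.10, and pufL and pufM turned to 0.14 and 0.04, none of these 3 past the threshold. Still falling were pufQ, pufX and puhA, with log2 changes of -0.67, -0.53 and -0.26. That scaling gives all arrays the same distribution, so it would also remove part of a real fall of the brightest genes.

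Photosynthesis regulators fell as a list. Of the 8 tested, 7 fell and 1, the sensor kinase gene prrB, rose (7 and 1 adjusted over the list alone), with a median log2 change of -0.76 and a camera adjusted p of 0.000306. That call had an adjusted p = 0.121 with an estimated correlation. The gene of the outer membrane protein TspO fell from 3510 ± 123 to 1418 ± 47 (SD, n = 3), a log2 change of -1.31, and ppaA from 1519 ± 189 to 627.9 ± 40.9, a log2 change of -1.27 (limma adjusted p = 2.64e-08 and 6.33e-07). The blue-light and redox sensor gene appA, its partner repressor gene ppsR and the oxygen regulator gene fnrL had log2 changes of -0.96, -0.77 and -0.53. These 3 genes have 5 probe sets each on the array, of which the brightest is given. The others of appA were lower by less, with log2 changes from -0.87 to -0.40, and the probe set at -0.40 did not pass the threshold (adjusted p of 0.0548), nor without the filter on intensity did that at -0.44. The log2 change of prrB was 0.52 with an adjusted p of 0.0104, and after median centring it was 0.37 with an adjusted p of 0.0737. Leaving out 10 W replicate 3 or 100 W replicate 1 also ended the call of prrB, with adjusted p of 0.0503 and 0.0559, as did leaving out the filter on intensity (0.0553).

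Of 11 bacteriochlorophyll synthesis genes, 3 fell (3 adjusted over the list alone) and 8 did not pass, with a median log2 change of -0.15. The cyclase gene bchE was at -0.42, which after quantile normalization became -0.26 with an adjusted p of 0.0538, and the methyltransferase gene bchM was at -0.39, which lost its call without 100 W replicate 2 (adjusted p of 0.0543). Of 7 haem and tetrapyrrole genes 3 fell (3 adjusted over the list alone), among them hemA, the gene of an aminolevulinate synthase, from 9690 ± 123 to 5219 ± 368 (SD, n = 3), and hemN, from 5223 ± 270 to 2944 ± 278. After median centring 4 of the list fell, and after quantile normalization 3 fell and 1 rose. The 4 carotenoid genes divided: crtA, the spheroidene monooxygenase gene, fell by 0.68 on the log2 scale, crtB, the phytoene synthase gene, rose by 0.65, and crtC rose by 0.35, while 1 did not pass (3 rose and 1 fell adjusted over the list alone). The rise of crtC was 0.19 with an adjusted p of 0.197 after median centring and 0.22 with an adjusted p of 0.122 after quantile normalization. Its call was also lost without 10 W replicate 1, 100 W replicate 2 or 100 W replicate 3 (adjusted p of 0.0529, 0.0617 and 0.0667). None of these 3 lists passed the camera threshold, with adjusted p of 0.228, 0.125 and 0.974.

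**Figure D2:**
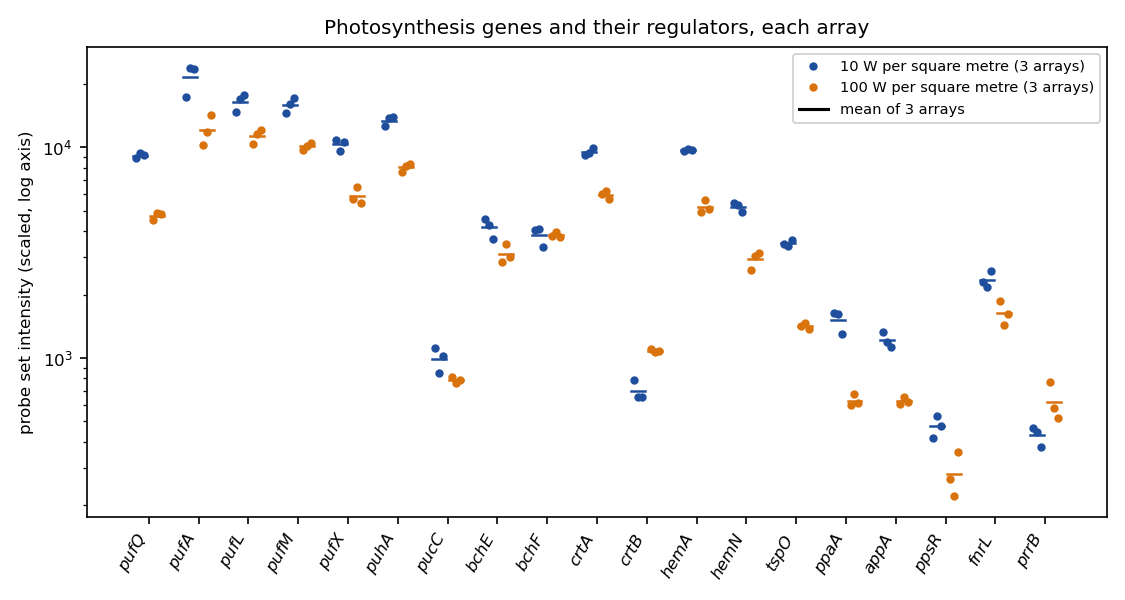
Intensity (log axis) of photosynthesis genes and their regulators on each of the 3 arrays at 10 W (blue) and at 100 W (orange), with the mean of each group as a bar. The intensities of tspO were 3510 at 10 W and 1418 at 100 W, while those of bchF were 3840 and 3829.

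All 9 named genes of NADH dehydrogenase rose (9 adjusted over the list alone), with a median log2 change of 0.61, among them nuoL (622.8 ± 50.3 to 1595 ± 61; SD, n = 3) and nuoN (499.5 ± 63.3 to 1272 ± 50). The camera adjusted p of the list was 0.0067, with an adjusted p = 0.176 with an estimated correlation. The 3 genes of the cbb3 oxidase rose (3 adjusted over the list alone), with ccoP at a log2 change of 0.68 and ccoO at 0.56, and the list did not pass (camera adjusted p = 0.354). After median centring 2 of them rose. The ATP synthase list held 2 copies each of atpA and atpD, which encode the catalytic core. The pair with gene IDs 3719828 and 3719830 rose by 0.95 and 0.87 on the log2 scale, and the dimmer pair with gene IDs 4796476 and 4796502 fell by 2.01 and 1.55 (2 and 2 adjusted over the list alone; camera adjusted p = 0.777). Of 7 genes of the TCA cycle 3 rose (3 adjusted over the list alone), among them sdhA with gene ID 3720729 at 0.66 and mdh at 0.54, and none fell, while sdhA with gene ID 3721439 was at 0.24 with an adjusted p of 0.442. The list did not pass (camera adjusted p = 0.777), and after median centring 2 of its genes rose. The list of cytochrome bc1 and c held 4 genes, ccmA, ccmB, ccmD and cycA, none of which encodes a bc1 subunit. Of these ccmA rose and cycA fell, with log2 changes of 0.49 and -0.705 (1 and 1 adjusted over the list alone). The median of 0.17 and the mean of 0.03 were positive and the test negative, against a median of 0.19 for all named genes (camera adjusted p = 0.777). The rise lost its call after median centring.

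Ribosomal protein genes divided. Of 45 tested, 20 rose, 9 fell and 16 did not pass (20 and 9 adjusted over the list alone), with a median log2 change of 0.17 and a camera adjusted p of 0.777. That is close to all 466 named genes tested, of which 181 rose and 94 fell, with a median of 0.19. The largest rises among them were those of rpsE (2416 ± 340 to 6284 ± 320; SD, n = 3) and rpmD (3000 ± 217 to 6945 ± 612). The steepest falls were those of rpsU, from 9991 ± 593 to 2431 ± 421, a log2 change of -2.05, and rpsT, from 12580 ± 1150 to 4294 ± 140, a log2 change of -1.55. The division went with probe set number. All the genes that rose except rpsI had numbers in the range from rplA to rplQ, and all that fell except rpsL lay outside it. Some that did not pass, among them rpsG, rplD and rpsK, lay inside too. Across the 45 genes, log2 change rose with gene length (Spearman's rho 0.36, permutation p = 0.0152, and genes are not independent replicates). After quantile normalization 31 rose and 6 fell, with a median of 0.51 and a camera adjusted p of 0.000507, and after median centring 19 rose and 11 fell. Quantile normalization raised bright probe sets as a whole. It moved the median of the 55 above a mean log2 intensity of 13 from -0.63 to 0.01, and that of the 98 between 12 and 13 from -0.06 to 0.14. Of 5 genes of RNA polymerase and sigma factors, rpoC and rpoB rose by 1.09 and 0.96 on the log2 scale and rpoZ fell by 0.47 (2 rose and 2 fell adjusted over the list alone, and after either other scaling). The gene of the sigma factor RpoE had a log2 change of -0.65 with a limma adjusted p of 0.0589, which was past the threshold in 5 alternatives, among them that without 10 W replicate 2 (adjusted p of 0.0348). The list had a camera adjusted p of 0.888, and its median of 0.13 turned to -0.02 after median centring.

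Among chaperones and proteases 3 of 9 genes rose and 3 fell (3 and 3 adjusted over the list alone), while 5 fell after median centring and 2 after quantile normalization. The chaperonin gene groEL (gene ID 3719842) went from 4625 ± 516 to 12030 ± 1780 (SD, n = 3) and dnaJ from 629.3 ± 56.1 to 1478 ± 178, while clpX fell from 3809 ± 180 to 2084 ± 253 and clpA had a log2 change of -0.38. The median of -0.23 and the test were negative and the mean of 0.16 was positive (camera adjusted p = 0.777). The call of clpA was lost without 10 W replicate 1 and without 100 W replicate 2, with adjusted p of 0.122 and 0.079, without the filter on intensity (0.0792) and without the intensity trend in eBayes (0.0723). Of 7 genes of oxidative and photo-oxidative stress 2 rose and 3 fell (2 and 4 adjusted over the list alone), against 1 and 4 after either other scaling, with gor, the glutathione reductase gene, at 0.69, grxC at -0.74 and trxA at -0.72. The gene trxB was at 0.45 and lost its call after either other scaling (log2 changes of 0.32 and 0.29) and without 10 W replicate 3, 100 W replicate 1 or 100 W replicate 3 (adjusted p of 0.139, 0.0658 and 0.119), without the filter on intensity (0.0908) and without the trend (0.0654). Of 5 iron genes, exbB and exbD were at 0.46 and 0.36, both calls being lost under either other scaling, and bfr (gene ID 3718670) and feoB fell by 0.94 and 0.92 on the log2 scale (2 and 2 adjusted over the list alone). The call of exbB was also lost without 10 W replicate 2 or 3 or 100 W replicate 1 or 3 (adjusted p of 0.14, 0.0663, 0.104 and 0.218), without the filter (0.107) and without the trend (0.0652), and that of exbD without 10 W replicate 1, 2 or 3 or 100 W replicate 1 or 3 (adjusted p of 0.1, 0.054, 0.076, 0.129 and 0.149). Of 15 DNA repair genes 6 rose and 1 fell (6 and 1 adjusted over the list alone), 4 rising after median centring and 5 after quantile normalization, with recQ at 1.69, lexA, the repressor gene of the SOS response, at 0.91 and recO at -0.57. The 1.69 of recQ had an adjusted p of 0.0908 without the filter on intensity and 0.0635 with the robust prior. Its 3.24-fold rise was 1.95-fold with the added intensity of 84.5, 5.01-fold without 10 W replicate 1 and 2.02-fold without 10 W replicate 2. The stress, iron and DNA repair lists had camera adjusted p of 0.354, 0.354 and 0.777, the iron median of -0.01 turned to 0.22 after quantile normalization, and the DNA repair median of 0.15 turned to -0.01 after median centring. None of the 4 genes tested of the hydrogenase list (hypB, hypD, hypE and hypF) passed the threshold. Their median of 0.05 was positive and the test negative (camera adjusted p = 0.777).

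**Figure D3:**
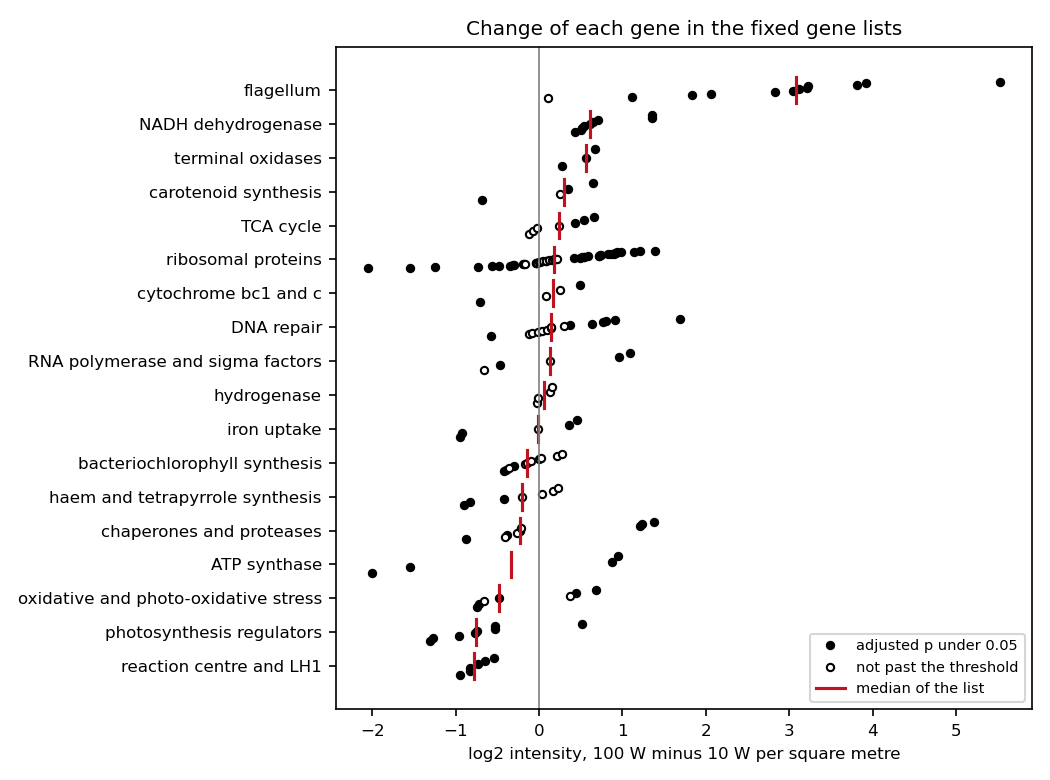
Log2 change (100 W minus 10 W) of each gene in the 18 gene lists with at least 3 tested genes, with filled points for genes past an adjusted p of 0.05 and a red bar for the median of each list. The flagellum list has a median of 3.08 and the reaction centre and LH1 list one of -0.78, which became -0.18 after quantile normalization.

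The other lists had fewer than 3 tested genes and no list test. The LH2 assembly gene pucC had a log2 change of -0.33, the Calvin cycle genes cbbX and cbbR of -0.33 and 0.42, the second of which did not pass, and the polyhydroxybutyrate synthase gene phaC of 1.52. Of 2 nitrogen fixation genes the activator gene nifA fell by 0.49 on the log2 scale. The 1 gene tested of the anaerobic reductase list, dorR, did not pass, and no chemotaxis gene was named. Outside the lists, the steepest falls among named probe sets above the filter on intensity were those of ctrA, the gene of a cell cycle response regulator, from 3076 ± 313 to 697.6 ± 34.6 (SD, n = 3), dksA, the gene of an RNA polymerase regulator of the stringent response, from 6043 ± 434 to 1564 ± 84, cysE (gene ID 3720098), from 1130 ± 64 to 379.6 ± 36.9, and pqqC, a gene of pyrroloquinoline quinone synthesis, from 233.8 ± 25.4 to 82.0 ± 4.1. Their limma adjusted p were 1.27e-09, 1.27e-09, 6.78e-08 and 4.75e-05.

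**Figure D4:**
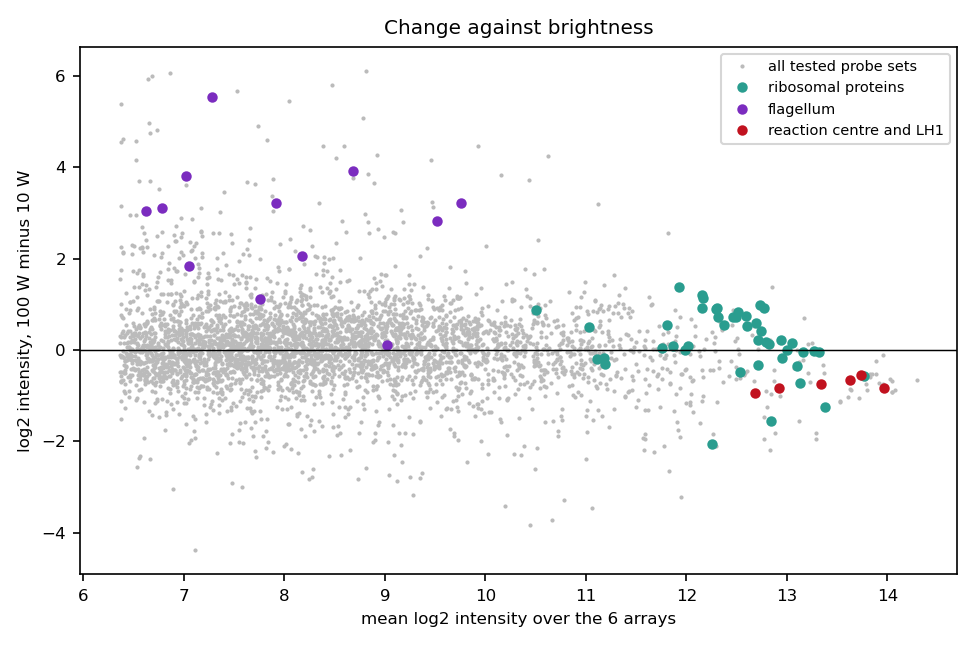
Log2 change (100 W minus 10 W) of the 4014 tested probe sets against their mean log2 intensity over the 6 arrays, with the ribosomal (green), flagellum (purple) and reaction centre and LH1 (red) genes marked. The 55 probe sets above a mean log2 intensity of 13, which include those of pufA, pufL, pufM and puhA, have a median change of -0.63, and 0.01 after quantile normalization.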

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

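The random draws of matched probe sets, the quantile normalization of the ribosomal genes that fell, the correlation with length within the ribosomal list and the length limit of 372 bases were tests chosen only after the results were seen. The 3 control probe sets for thrC of Bacillus subtilis, which lie outside the comparison of Rhodobacter sphaeroides genes, differed between the groups. With the floor applied, their log2 intensity differed by -2.49, -2.45 and -2.29 (probe sets 21, 22 and 23), from 112 ± 34.1 to 20.03 ± 10.7, from 70.1 ± 4.1 to 7.4 ± 4.5 and from 78.77 ± 20.4 to 14.97 ± 7.4 (SD, n = 3 arrays), with no overlap between the groups. All 3 of the 100 W arrays of probe set 22, and 1 each of probe sets 21 and 23, were below the floor of 12.8, so the floor limits these differences, and that of probe set 22 is set by it.

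With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 2118 changed probe sets and 715 changed at least 2-fold, and the highest of the other splits gave 0 for each (1 of 10 splits was as large in both). For gene lists the real split gave 4 and the highest other split 7, and 4 of the 10 splits gave as many, so that as many list calls also arose where no single probe set passed. Each other split mixed the light levels unevenly on both sides, so it kept part of the light contrast and added spread within its groups. The counts of the other splits, of probe sets and of lists, therefore do not measure what would arise without a difference between the groups.

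The fall of the reaction centre and LH1 genes was set against a compression of bright probe sets on the 100 W arrays. Probe sets outside the photosynthesis lists matched to them in intensity had a median log2 change of -0.52 (SE 0.10, 77 probe sets), against -0.78 (SE 0.07) for the 6 genes. That gap of 0.26 was beyond the bound set in advance, which would have counted against compression, but the bound left out the spread of the matched probe sets; of 10000 random matched sets drawn afterwards, 15.2% were as low, so compression was left open on a rule changed after the result was known. Quantile normalization, which removes any curve in intensity, left a median of -0.18 (SE 0.16). It gives all arrays the same distribution, so it would also remove part of a real fall of the brightest genes and cannot tell these apart. There pufQ, pufX and puhA stayed past the threshold, at -0.67, -0.53 and -0.26. The changes of pufA (probe set 1130), pufL and pufM went from -0.83, -0.54 and -0.65 (SE 0.14, 0.10 and 0.09) to -0.10, 0.14 and 0.04, and these calls ended. Of the other pufA probe sets, 1129 kept its call at -0.25 (limma adjusted p of 0.049), and 1126, 1127 and 1128 lost theirs. The scaling and a curve in intensity therefore stay open for the 6 genes as a set, as does a response to light, which the design names but which coincides with bulb type and month.

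For the flagellum genes, array scaling and the floor were argued against, since the lowest median log2 change over 4 scaling and floor settings was 2.10. Another difference between the cultures stays open: of the batches by month or bulb in the labels, 0 held both groups, so that no value within a batch can be had and light and batch cannot be told apart.

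The ribosomal protein genes that fell (9, median log2 change -0.57) were set beside those that rose (20, median 0.78). Lower recovery of short transcripts at 100 W stays open: over 363 named genes outside the list, Spearman's rho of gene length and log2 change was 0.089 (permutation p = 0.0915, across genes, which are not independent), under but close to the bound of 0.1 set in advance, while within the 45 ribosomal genes it was 0.36 (permutation p = 0.0152). The other bound set in advance was a median at or above 0 for short genes outside the list. It was met with 0.15 (SE 0.10) for 101 genes of up to 762 bases, but that limit came from rpsB alone. Of the 19 genes no longer than 372 bases, the length that takes in 8 of the 9, 12 fell and 4 rose, with a median of -0.52 (SE 0.29). Both bounds were met, and either alone would have counted against this explanation, so it was left open on a rule changed after the result was known. These lengths are of single genes, and a transcript can span several, so they cannot decide on the recovery of short transcripts. Compression stays open too, since probe sets matched to the 9 in intensity had a median of -0.50 and quantile normalization left the 9 at -0.26 (SE 0.27), with 6 still past the threshold. A difference in growth rate or density at harvest may also be at work and was not tested. The division also went with probe set number: the genes that rose, except rpsI, lay in the range from rplA to rplQ. Those that fell, except rpsL, lay outside it. Length and probe set number were not tested apart from each other, and the permutation over single genes takes no account of that range.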

How the results depend on the processing

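The background of the list test, the 466 named genes, was settled after the values were seen, and the other background, all tested probe sets, was also chosen after seeing the data and called 4 lists too. The number of changed probe sets stayed within 1.5 times of 2118 under each setting run (1844 to 2068 with an array left out), of which quantile normalization shared 1923 of its 2212 and median centring 1852 of its 2145. With an array left out, the ranges were 1020 to 1194 higher, 824 to 941 lower, 689 to 752 at least 2-fold, 396 to 433 of these higher and 287 to 330 lower, and 4 lists. With the lower 50% of probe sets left out, 447 changed at least 2-fold and 225 of these were higher, since fewer and brighter probe sets were tested, and with the pseudocount 201 were at least 2-fold lower, since it shrinks dim changes. Camera with an estimated correlation called 0 lists (18 were tested, with 4 under the preset one and 11 by fry, which asks another question: whether the genes of a list move one way). At an unadjusted p under 0.05, 3 lists passed with the estimated correlation. After quantile normalization pufL turned to 0.14 and pufM to 0.041, and the ribosomal list gained a call (adjusted p of 0.000507; 0.101 to 0.934 over its other settings). Of 937 alternatives for 63 named probe sets, 889 kept their direction and side of the threshold, 41 lost the call, 5 gained one and 2 reversed, and 50 probe sets never left their call. Replicate numbers gave no pairing: same-numbered arrays deviated with r of 0.13, -0.01 and -0.03, and 10 W replicate 2 correlated best with 100 W replicate 3 (0.14). The replicate block called 2113 probe sets, 1170 higher and 943 lower, 2068 of them shared, 718 at least 2-fold (414 higher, 304 lower), and 4 lists, and among the named results it ended only the call of exbD (adjusted p of 0.0605, 0.0448 without the block). The stricter threshold of 0.01 was run for counts of probe sets alone, the robust prior not for lists, and the comparison of replicons was not run. Signal over background cannot be judged without detection calls, so folds of probe sets near the floor carry the widest doubt.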

Other observations

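The groups and the probe sets described here were picked after their values were seen, except that the test of flaF and flbT was set in advance. All 5 named genes of isoprenoid precursor synthesis, the pathway that feeds carotenoids and the bacteriochlorophyll tail, fell at 100 W: dxs, dxr, ispD, gcpE and lytB had log2 changes between -0.84 and -0.69, and between -0.90 and -0.72 after quantile normalization. The intensity of dxs went from 1341 ± 104 to 752.3 ± 92.9 and that of lytB from 2426 ± 113 to 1432 ± 166 (SD, n = 3). The genes of the glycine cleavage system gcvT, gcvH and gcvP rose by 0.58 to 1.38 on the log2 scale, and of the conjugation genes traL, traU, traF and trbC all 4 rose, by 1.89 to 3.70. The leucine genes leuB, leuC and leuD rose by 1.15, 0.93 and 1.14. Among 16 families of at least 4 genes that share the first 3 letters of their symbol, camera called 0 after adjustment and 1 at an unadjusted p under 0.05.

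Without the filter on intensity, rpoN (gene ID 3718440), the gene of a sigma-54 factor, was at 296.6 ± 79.4 at 10 W and 13.8 ± 6.5 at 100 W, where 2 of 3 arrays were below the floor of 12.8. Of the pyrroloquinoline quinone genes pqqB, pqqC, pqqD and pqqE all 4 fell in that fit, pqqB from 182.8 ± 36.2 to 19.3 ± 5.4. The gas vesicle gene gvpA fell from 161.3 ± 26.1 to 64.3 ± 15.1.

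The fall of ctrA beside the rise of the flagellum genes raised the hypothesis of a second flagellar gene set that follows ctrA, which would have lowered flaF and flbT at 100 W. Their mean log2 change was -0.039: flaF was below the floor on all 6 arrays and flbT was at 74.3 ± 17.8 and 69.1 ± 3.4, so these dim probe sets decide nothing for or against it.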
